A study of Mus musculus with 2 samples.

How the data were processed

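The series holds 2 replicate ChIP-seq libraries of H3K4me3 from MEL cells, 1 group with no other condition. The size range in the labels is 150 to 350 bp. The deposited data used here are 5 peak lists: 1 per replicate, 1 from both replicates pooled, 1 of replicated peaks, all on mm10, and 1 on mm9. Per the notes deposited with the samples, each replicate list was derived from that replicate's alignments and a control, the pooled list from the alignments of both replicates and the control, and the replicated list from the other 3. Every row of the replicated list was found in the pooled list with the same position and values. The rule by which a peak counted as replicated, the aligner, the peak caller and its settings are not given in the sources used here. The origin of the mm9 list is not given either.

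All lists are in narrowPeak format, per the deposited notes. The peak signal value is a score for each peak made by the authors, whose exact definition is not given in the sources used here. The authors also give −log10 p and −log10 q for each peak, and the position of the summit. The lists hold weak peaks: 4.69% of the replicate 1 and 3.72% of the replicate 2 peaks had a q-value above 0.05, as did 1.77% of the replicated peaks. The lists hold no read counts, so the depth of each library and the precision it gives are unknown, and a missing peak can mean too few reads. Signal values were used only to rank or filter peaks within a list.

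From the deposited lists, peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on other contigs, 8 in the replicated list, are counted separately. Overlaps of at least 1 bp were found with bedtools 2.31.1. For random placement, each peak was moved 100 times to a random position on its chromosome. Genes and TSSs came from the GENCODE annotation M21 on GRCm38, the same build as mm10, with 21938 protein-coding genes and 93513 TSSs. A gene was called marked where a replicated peak lay within 1000 bp of any of its TSSs. A peak between neighbouring genes counted for each of them. Promoter class was taken from 1001 bases around the 5'-most TSS of each gene. High-CpG promoters had an observed to expected CpG ratio of at least 0.6 and a GC share of at least 0.5, and low-CpG promoters had a ratio under 0.4. Sequence found elsewhere was measured as the percent of 32-base words of the same promoter that occur more than once on either strand of the genome. TSS domains are replicated peaks merged across gaps of up to 1000 bp.

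Shares were compared with two-sided Fisher's exact tests, over genes or peaks, which are not independent replicates. The 23 gene lists, the tests and most alternatives were fixed before the data were examined, and p-values were adjusted over the lists with the Benjamini-Hochberg method. Widths were compared by a two-sided permutation test of the difference of medians with 100000 resamples, and summit positions with an exact binomial test. Lists matched on promoter CpG class were drawn 100000 times. Of the listed genes, 2 globin genes and Ahsp, of the erythroid membrane and effector list, were not found under their symbols in the annotation. The list test was run on simulated data with marks drawn independently for each gene. Among 500 random lists over the 21938 genes it called 4.8% at 0.05. It called 100% of lists made with 18 of 20 members marked, which their makeup fixed in advance, so that share does not measure power. The simulated marks did not depend on promoter CpG class, as the real ones do. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9.

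The genes named were chosen by a rule fixed beforehand: all members of the globin, erythroid transcription factor and Friend erythroleukaemia lists; from every other list, the 2 with the widest TSS domain and the first 2 without a TSS peak; the 10 with the widest domains; the 10 with the highest signal value; and for each replicate the 5 with the highest signal value marked in it alone. Alternatives were TSS windows of 500 and 2500 bp, the 5'-most TSS alone, peaks with −log10 q of at least 5, the pooled list or either replicate list in place of the replicated list, overlap of 50% of 1 or both peaks, equal numbers of the strongest peaks, other gaps and another width limit. Added after the data were seen were promoters with under 10% repeated words, peaks given to the nearest TSS only, and overlap of merged peaks. The mm9 list was described and not compared with mm10.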

Results

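Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active and poised promoters, was mapped by ChIP-seq in MEL cells. MEL is an immortalized mouse erythroleukaemia line, whose cells resemble red cell precursors stopped before terminal differentiation. The data were 2 replicate libraries of 1 group, with no second condition, so the comparisons made were between the replicates and between classes of genes. On the mm10 genome, 51790 peaks were listed for replicate 1, 41508 for replicate 2, 41075 for both replicates pooled and 37387 as replicated peaks. The replicated list covered 31.3 Mb, or 1.15% of chromosomes 1 to 19, X and Y, and its median peak width was 603 bp. Numbers of reads were not in the lists, so the depth behind each peak is unknown. The labels call the libraries biological replicates 1 and 2 and name the same cell sample for both, so what the spread between them covers is unclear, and p-values across genes or peaks describe these lists.

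The replicates marked nearly the same genes. Of 21938 protein-coding genes, 10964 had a peak within 1000 bp of a transcription start site (TSS) in both replicate lists, 87 in replicate 1 alone and 212 in replicate 2 alone, so that 98.6% of genes had the same call. Among single peaks the lists differed more. Replicate 2 overlapped 77.5% of the replicate 1 peaks, and replicate 1 overlapped 84.0% of the replicate 2 peaks, against means of 2.04% and 2.33% when the peaks were placed at random. None of 100 random placements reached either value. The Jaccard index, the bases in both lists divided by the bases in either, was 0.707.

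Overlap followed peak strength within each list. In replicate 1 it was 38.3% in the weakest decile by peak signal value and 99.98% in the strongest, and in replicate 2 it was 66.1% and 100%, with the lowest value, 63.2%, in decile 3. The replicated list kept 91.0% of the pooled peaks. It held every pooled peak of the strongest 5 deciles and 59.3% of the weakest. Of the 3688 pooled peaks it left out, 4.20% were overlapped by both replicate lists, against 92.7% of those kept. Since the replicated list was derived from the replicate and pooled lists, this contrast reflects how it was made and is no separate measure of agreement.

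**Figure D1:**
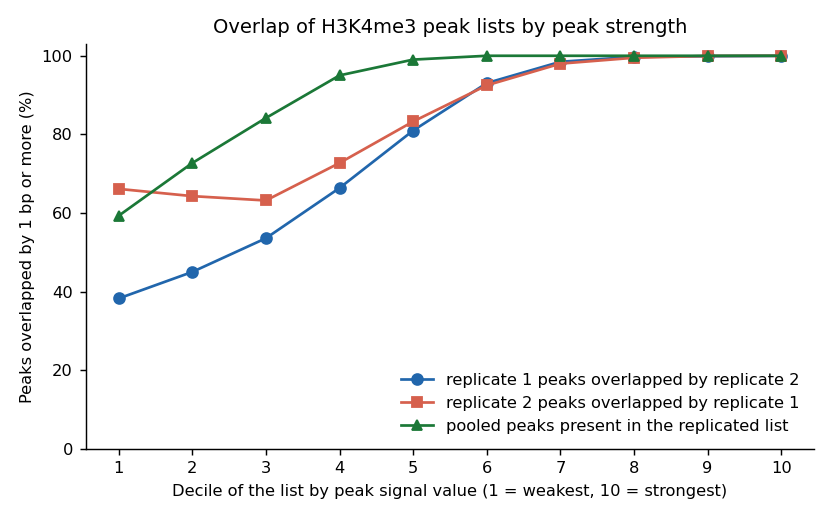
Share of peaks (y axis, percent) overlapped by 1 bp or more, for each decile of a list by its own peak signal value (x axis, weakest to strongest). Circles are replicate 1 peaks against replicate 2, squares replicate 2 peaks against replicate 1, and triangles pooled peaks present in the replicated list. Overlap of replicate 1 peaks rose from 38.3% in the weakest decile to 99.98% in the strongest.

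Peaks found in both replicates lay at promoters more often than peaks of 1 replicate. In replicate 1, 53.1% of 40144 shared peaks and 11.3% of 11637 unshared peaks lay within 1000 bp of a protein-coding TSS. In replicate 2 the shares were 48.5% of 34841 and 15.9% of 6660. In both lists the two-sided Fisher's exact p was too small for the software to represent. The unshared peaks were narrow, with median widths of 193 bp in replicate 1 and 197 bp in replicate 2, against 564 bp and 621 bp for shared peaks.

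Some genes had a TSS peak in 1 replicate list only. The 5 with the highest signal value at a TSS in replicate 1 and no TSS peak in replicate 2 were Pilrb2 (7.50), Calhm5 (7.11), Btn2a2 (6.67), Nxpe2 (5.88) and Plekha5 (5.75), against a median of 5.23 over all replicate 1 peaks and a maximum of 33.4. The 5 of replicate 2 alone were Cfap69 (12.1), Slc17a1 (11.4), Trnp1 (11), Iqsec2 (10.7) and Pdzd4 (10.3), against a median of 5.99 and a maximum of 49.0 in that list. Signal values were ranked only within a list. The replicated list held a TSS peak at Btn2a2, Nxpe2 and all 5 genes of replicate 2, and none at Pilrb2, Calhm5 and Plekha5. A gene with a TSS peak in 1 replicate list can thus count as marked in the replicated list.

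About as many protein-coding genes had an H3K4me3 peak at the TSS as did not. The replicated list marked 11037 of 21938 genes, or 50.3% (exact 95% binomial interval 49.6 to 51%), and the replicate lists marked 50.7% ± 0.403 (SD, n = 2). Seen from the peaks, 49.3% of the replicated peaks lay at a protein-coding TSS, against a mean of 5.30% in 100 random placements and a highest value of 5.52%. These peaks held 68.1% of all bases in the list. Of all replicated peaks, 4.13% lay only at a TSS of another gene type, and those at no TSS had their summit in an exon (2.27% of all), in an intron (21.3%) or between genes (23%).

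Promoter peaks were broad, and at most of the genes tested their summit lay downstream of the start site. Peaks at a protein-coding TSS had a median width of 1000 bp and the rest 379 bp, a difference of 621 bp (two-sided permutation p = 1e-05 over 37379 peaks, the smallest that 100000 resamples can give). At 8441 genes with no protein-coding TSS of the opposite strand within 2000 bp, the summit of the strongest TSS peak lay downstream of the nearest TSS in 6196 and upstream in 2238. The downstream share was 73.5% (exact 95% interval 72.5 to 74.4%), with an exact binomial p against equal shares too small to represent. The median summit lay 114 bp downstream, and the middle range of genes, from the first to the third quartile, ran from -26 to 317 bp.

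**Figure D2:**
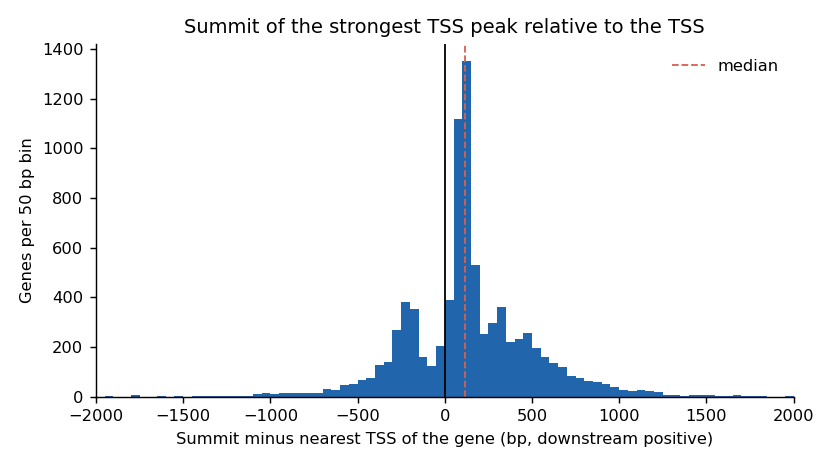
Number of genes per 50 bp bin (y axis) by the distance in bp from the nearest TSS of the gene to the summit of its strongest TSS peak (x axis, downstream positive), in the replicated list. The solid line is the TSS and the dashed line the median of 114 bp, and a smaller group of summits lies upstream of the TSS.

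The regulators of the red cell lineage were all marked. All 12 erythroid transcription factors had a TSS peak in the replicated list and in each replicate list, against 50.3% of other genes (two-sided Fisher's exact test, p adjusted over 23 gene lists = 0.000935). They were Gata1, the master regulator of the lineage, with its cofactor Zfpm1 and partners Tal1, Lmo2 and Ldb1; Klf1 and Nfe2, which drive globin transcription; and Gfi1b, Cbfa2t3, Zbtb7a, Foxo3 and Bcl11a, a repressor of embryonic globin. The strongest TSS peak of Gata1, on chromosome X from 7964465 to 7967884, had a signal value of 20.6 and its summit in an intron. That of Tal1 (chromosome 4, 115056763 to 115060815, 20.2) also had its summit in an intron, and that of Klf1 (chromosome 8, 84901951 to 84903508, 15.3) in an exon. With only the 5'-most TSS of each gene, 91.7% of the list was marked. The gene lost was Gata1, whose 5'-most TSS lies at 7978071, while its domain ended at 7971910, so its peaks lay at an internal TSS. Random lists with the same promoter CpG classes averaged 48.2% (permutation p adjusted over the lists = 3.8e-05).

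Genes of haem synthesis and of the red cell membrane were marked nearly as completely. TSS peaks were present at 14 of 15 genes of haem synthesis and iron uptake (93.3%, exact adjusted p = 0.0016). Among them, Slc11a2, which carries iron into the cytosol, and Cpox, a porphyrin pathway enzyme, had the widest domains, 4701 bp and 4654 bp. The Slc11a2 peak also lay at the TSS of Gm5475, and with nearest-TSS assignment Slc11a2 was unmarked and the list share 86.7% (exact adjusted p = 0.00479). The exception was Slc25a37, the mitochondrial iron importer, at whose promoter each 32-base word of sequence occurs more than once in the genome. Of 21 erythroid membrane and effector genes, 19 had a TSS peak (90.5%, exact adjusted p = 0.000462), led by Car1, a carbonic anhydrase, and Epb41, which encodes a protein of the membrane skeleton and shares its peak with Gm10300. No TSS peak was listed for Slc4a1, the anion exchanger of the red cell membrane, in any of the mm10 lists. Of the 32-base words of its promoter, 12.3% occur more than once in the genome, so loss of shared reads is not excluded. Epb42, a membrane skeleton gene, had a weak peak in each replicate list (signal values 3.07 and 3.28) but none in the pooled or the replicated list.

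Most globin genes had no TSS peak. Of 10 annotated globin genes, 3 had a TSS peak (30.0%, exact 95% interval 6.67 to 65.2%), which did not differ from other genes (exact adjusted p = 0.257). None has a high-CpG promoter, and lists with the same CpG classes averaged 23.9% (permutation adjusted p = 0.755), so the share lay below that of other genes and above that of matched lists, without a call in either. The peaks lay at Hbb-bt, an adult beta-globin gene (chromosome 7, 103813815 to 103814504, signal value 5.37), at Hba-a1, an adult alpha-globin gene (chromosome 11, 32283179 to 32283432, 3.66), and at Hbq1b (chromosome 11, 32287451 to 32287922, 7.30). The same 3 genes were marked in each replicate list. By signal value these peaks ranked 10642nd, 10917th and 10198th among the 11037 marked genes. The adult copies Hbb-bs and Hba-a2, Hbq1a, and the embryonic or fetal genes Hbb-y, Hbb-bh1, Hbb-bh2 and Hba-x had none. The promoters of Hba-a1 and Hba-a2 consist to 88.0% and 93.2% of 32-base words that occur elsewhere in the genome, those of Hbq1b and Hbq1a to 43.6% and 43.7%, and those of Hbb-bt and Hbb-bs to 30.2% and 20.8%, so the calls at all 3 pairs of copies are uncertain. An alternative chosen after the data were seen kept only globin genes with under 10% of such words. It left 4 genes, Hbb-bh2, Hbb-bh1, Hbb-y and Hba-x, all embryonic or fetal, none of them marked (exact adjusted p = 0.0462), so it holds no adult globin gene.

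**Figure D3:**
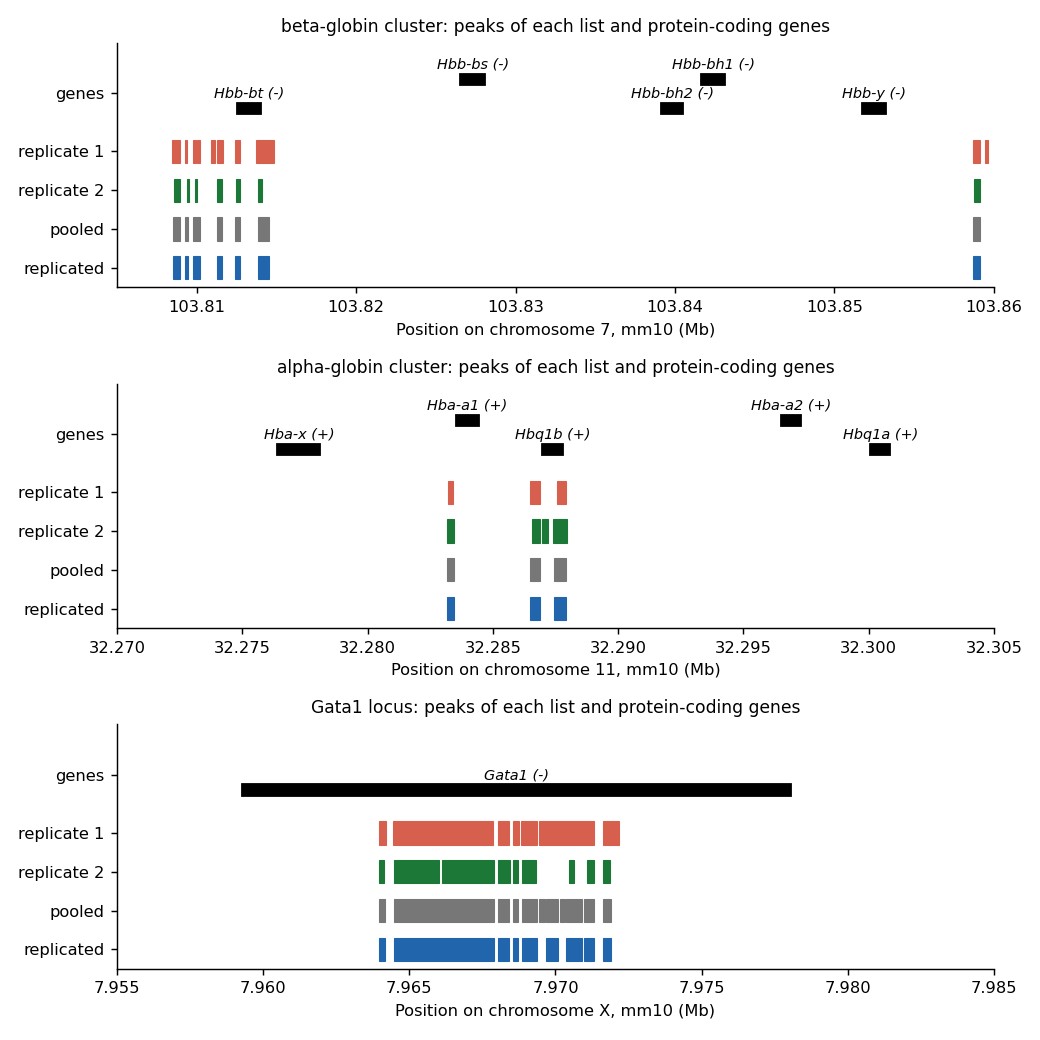
Peaks of the replicate 1, replicate 2, pooled and replicated lists (coloured boxes, y axis) and protein-coding genes with their strand (black boxes) by position in Mb on mm10 (x axis) at the beta-globin cluster, the alpha-globin cluster and Gata1. Every list has peaks at Hbb-bt, Hba-a1 and Hbq1b, none at Hbb-bs or Hba-a2, and a run of peaks over the middle of Gata1 that spans 7953 bp, gaps included, as 1 merged domain in the replicated list.

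Of 8 genes tied to Friend virus erythroleukaemia, 7 had a TSS peak (87.5%), short of the threshold (exact adjusted p = 0.0851). The call was gained with TSS windows of 500 or 2500 bp, with the 5'-most TSS alone, with a stricter q, with each peak given to the nearest TSS only and in the replicate 1 list. Spi1, the transcription factor gene activated by the virus in this disease, had its strongest TSS peak in an intron (chromosome 2, 91096746 to 91099548, signal value 13.2). Fli1, another ETS factor gene, Myc, Myb, Trp53, Mst1r and the erythropoietin receptor gene Epor were also marked, the Trp53 peak shared with Wrap53. Kit, the stem cell factor receptor gene, had a TSS peak in replicate 1 only, although the replicated list held 6 peaks inside the gene, the strongest on chromosome 5 from 75623804 to 75624421.

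Stem cell and megakaryocyte genes were marked in part. TSS peaks were found at 6 of 14 stem and progenitor genes (42.9%, exact adjusted p = 0.632), with the widest domains at Myb and Meis1, while Kit and Hoxa9 had none. Of 13 megakaryocyte markers 6 had a TSS peak (46.2%, exact adjusted p = 0.789), widest at Gp5 and Pf4. Gp6 and Gp1bb had none. Lists with the same CpG classes averaged 61.2% for the stem and progenitor genes and 25% for the megakaryocyte markers, so the latter lay above their matched lists, again without a call (permutation adjusted p = 0.157 and 0.112).

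Markers of other cell types were mostly unmarked. Of 160 marker genes of 9 other cell types, the megakaryocyte genes included, 31 had a TSS peak (19.4%), and at 6 of these the peak also lay at the TSS of another gene. No peak lay at the 20 liver markers, Alb and Ttr among them (exact adjusted p = 3.2e-06), although a 2500 bp window found one at 15% (exact adjusted p = 0.00183). Of 21 muscle markers 2 were marked, Ckm and Des, the Ckm peak shared with Klc3, while Myog and Myod1 were not (exact adjusted p = 0.000282). Of 21 neuronal markers 3 were marked, with Neurog2 and Syp the widest, and Snap25 and Syt1 were not (exact adjusted p = 0.00141). Of 20 germ cell genes 4 were marked (exact adjusted p = 0.00985), including Gdf9 and Tex14, whose peaks also lay at the TSSs of Uqcrq and Rad51c, whereas Sycp1 and Ddx4 had none. The muscle share was 4.76% with the 5'-most TSS, a stricter q or nearest-TSS assignment, and the germ cell share 10% with a stricter q, with the calls kept.

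Markers of other blood lineages, vessels and fibroblasts were also marked in part. TSS peaks lay at 4 of 20 lymphoid markers (exact adjusted p = 0.00985), widest at Gata3, which shares its peak with 9230102O04Rik, and Lck, and absent at Cd3g and Cd3e. They lay at 4 of 17 myeloid markers (exact adjusted p = 0.0404), widest at Prtn3 and Cebpa and absent at Elane and Mpo. Cebpa had no TSS peak in replicate 1, and its replicated peak was weak (signal value 4.25, ranked 10825th among marked genes). The Elane promoter holds 22.7% repeated words, so its call is uncertain. Of 14 endothelial markers 3 were marked (exact adjusted p = 0.0435), among them Egfl7, which shares its peak with Gm20532, and Esam, but not Kdr or Cdh5. Fibroblast markers were marked at 5 of 14 genes, widest at Pdgfrb and Col1a1 and absent at Col3a1 and Col1a2, and did not differ from other genes (exact adjusted p = 0.327) or from CpG-matched lists, which averaged 32.7% (permutation adjusted p = 1). With a stricter q the fibroblast share was 21.4%. With the 5'-most TSS alone the lymphoid share was 10% and the endothelial share 7.14%, with the calls kept. The myeloid and endothelial calls ended with a 2500 bp window (exact adjusted p = 0.259 and 0.138), the myeloid call also with nearest-TSS assignment (0.0645), and the endothelial call with a stricter q (0.0661) and in the replicate 1 list (0.14). Against random lists with the same promoter CpG classes, the lymphoid, myeloid, endothelial, liver and muscle lists no longer passed the threshold (permutation adjusted p = 0.467, 1, 0.131, 0.054 and 0.0501), while the neuronal and germ cell lists did (3.8e-05 and 0.044).

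Pluripotency and Hox genes stood below their promoter class. None of 14 pluripotency genes was marked, Pou5f1 and Nanog included (exact adjusted p = 0.00016), where lists with the same CpG classes averaged 41.2% (permutation adjusted p = 0.00103). Of 39 Hox genes 8 were marked (20.5%, exact adjusted p = 0.000382) against 65.8% in matched lists (permutation adjusted p = 3.8e-05). The widest were Hoxc6 and Hoxc9, both on chromosome 15, and Hoxd13 and Hoxd12 had no TSS peak. Among 1093 olfactory receptor genes, which are expressed in sensory neurons of the nose, 6 were marked (0.549%), or 0.274% with a 500 bp window. Of these, Olfr221 and Olfr56 had the widest domains, and the Olfr56 peak also lay at the TSS of Ifi47, while Olfr1416 and Olfr1415 had none.

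The listed ribosomal protein, cell cycle, housekeeping and H3K4 methylation genes were all marked, and most of the histone genes were. TSS peaks lay at 76 of 76 ribosomal protein genes (exact adjusted p = 2.97e-22), 26 of 26 genes of the cell cycle and DNA replication (2.28e-07), 24 of 24 housekeeping genes (5.47e-07) and 16 of 16 genes of the H3K4 methylation machinery (0.0001), in the replicated list and in both replicate lists. The widest domains were at Rpl36a and Rpl35, which share their peaks with Btk and Arpc5l, at Mki67 and Rrm1, at Ywhaz and Tubb5, and at Setd1b and Kmt2d, which encode H3K4 methyltransferases. Replication-dependent histone genes were marked at 55 of 67 (82.1%, exact adjusted p = 5.47e-07), widest at Hist1h4h and Hist1h2af, which lie on the same domain of 7224 bp. Hist3h2ba and Hist1h2bq had no peak, and 22.9% and 100% of the words of their promoters occur elsewhere in the genome. The histone share depended on the peak assignment. It was 64.2% with a 500 bp window (exact adjusted p = 0.0251) and 71.6% with nearest-TSS assignment (0.000283), with the call kept. With the 5'-most TSS alone it was 82.1%, and with a 2500 bp window 83.6%. Many of these genes share a peak with a neighbouring histone gene. The histone call ended against CpG-matched lists, which averaged 72.1% (permutation adjusted p = 0.0892), and among the fewer promoters with under 10% repeated words, where the share stayed at 80% (exact adjusted p = 0.222).

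**Figure D4:**
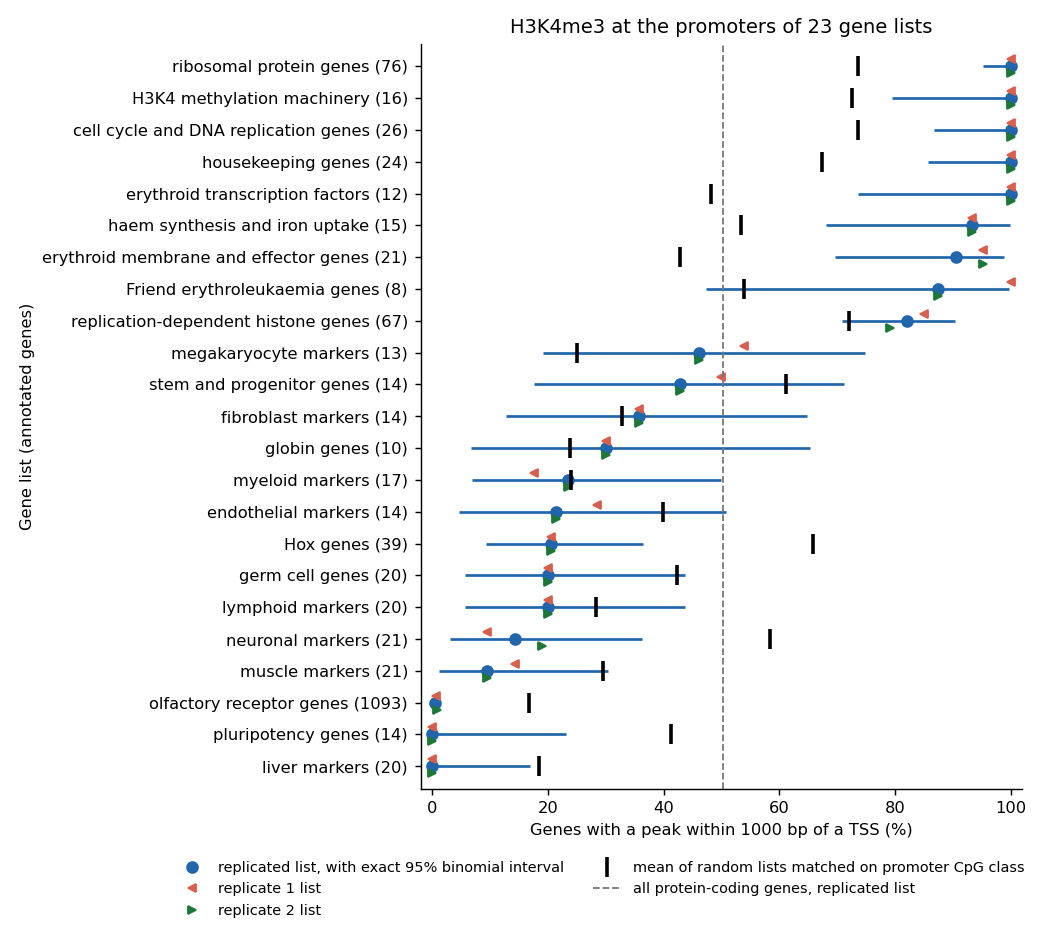
Share of genes with a peak within 1000 bp of a TSS (x axis, percent) for 23 gene lists (y axis, number of annotated genes in brackets). Circles with bars are the replicated list with exact 95% binomial intervals, triangles the replicate lists, short black strokes the mean of random lists matched on promoter CpG class, and the dashed line all protein-coding genes (50.3%). All 12 erythroid transcription factors were marked, and 3 of 10 globin genes.

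Most of the erythroid regulators had wide domains. Replicated peaks were merged across gaps of up to 1000 bp, and each marked gene was given its widest TSS domain, with a median of 2258 bp. The widest 5% comprised 553 genes with domains of at least 4864 bp. Of the 12 erythroid transcription factors 9 were among them (75%, against 4.93% of other marked genes, exact p adjusted over 14 lists = 5.03e-09), and their median domain was 5804 bp wide. The domain of Bcl11a spanned 10514 bp, that of Ldb1 9936 bp, that of Nfe2 9648 bp, that of Foxo3 8183 bp and that of Gata1 7953 bp. Cbfa2t3, Gfi1b, Zbtb7a and Zfpm1 were also in the widest 5%, and Tal1, Klf1 and Lmo2 lay below it at 4631, 4007 and 3895 bp.

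The erythroid membrane and effector genes were the other list past the threshold, with 5 of 19 wide (26.3%, exact adjusted p = 0.014). That call ended in the replicate 1 list, with no gap or gaps of up to 3000 bp merged, and with the widest 10% of genes. Of the Friend erythroleukaemia genes 2 of 7, Myc and Myb, were wide (28.6%, exact adjusted p = 0.125). That list passed the threshold in each replicate list, with 57.1% in replicate 2 and 37.5% in replicate 1. None of the 14 marked haem and iron genes was wide, although 21.4% were in the replicate 1 list (exact adjusted p = 0.0701).

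**Figure D5:**
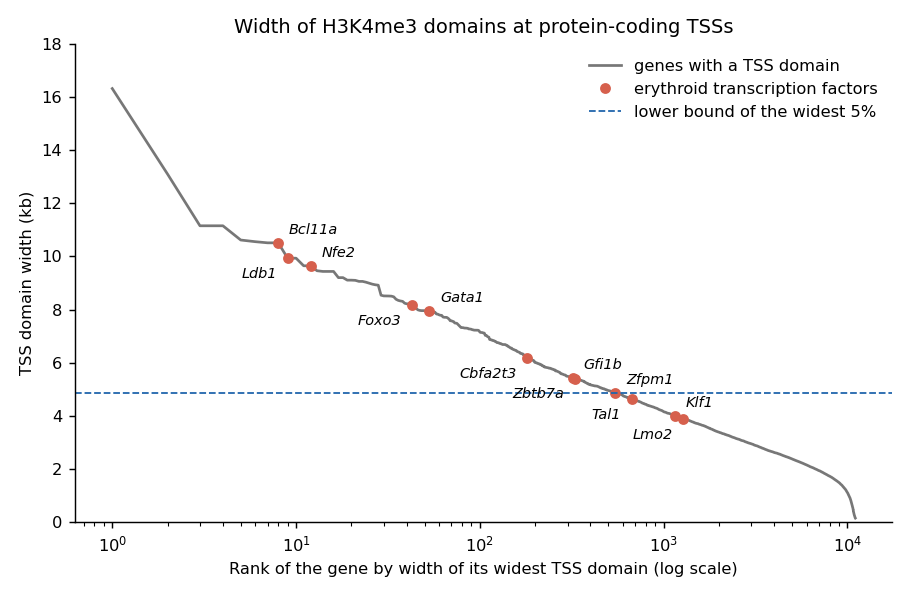
Width in kb of the widest TSS domain of each of 11037 marked genes (y axis) by rank (x axis, log scale). Points are the 12 erythroid transcription factors, and the dashed line is the lower bound of the widest 5% at 4864 bp, with 9 of the 12 above it.

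The 10 genes with the widest domains were Abt1 (16322 bp), Car1 (13100 bp), Nfia and E130114P18Rik on the same domain (11156 bp), Irf2bp2 (10620 bp), Gse1 (10557 bp), Bcl11a and A830031A19Rik on the same domain (10514 bp), and Ldb1 and Pprc1 on the same domain (9936 bp). The domain of Abt1, on chromosome 13 from 23423196 to 23439517, was built from 14 peaks, and that of Bcl11a was a single peak on chromosome 11 from 24073830 to 24084343. The Car1 domain ran from 14796317 to 14809416 on chromosome 3 and joined 7 peaks. The 10 genes whose TSS peak had the highest signal value were others: Syap1 (36.0), Drap1 and AI837181 at the same peak (35.3), Xaf1 (34.0), Trafd1 (33.9), Plekhm2 (33.5), Aifm2 (33.2), Carnmt1 (32.5), Ap3b1 (32.4) and H2-M3 (32.3). Their domains were 965 to 3155 bp wide. Of the 32-base words of the promoters of Syap1, Carnmt1 and Trafd1, 30.1%, 23.4% and 10.9% occur more than once in the genome. Reads from elsewhere are thus not excluded at these genes, and the other promoters hold under 10% of such words.

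Promoter sequence class separated marked from unmarked genes. A TSS peak was found at 79.8% of 9738 genes with a high-CpG promoter (exact 95% interval 79.0 to 80.6%), 53.0% of 3415 with an intermediate one and 16.6% of 8785 with a low-CpG one. High-CpG and low-CpG genes differed by 63.2 percentage points, and the two-sided Fisher's exact p was too small to represent. The replicate lists gave 79.7 and 80.2% for high-CpG and 17.0 and 17.5% for low-CpG genes. The class was taken at the 5'-most TSS, while a peak at any TSS counted, so the marked TSS can differ from the classed one. That limit also holds for the lists matched on promoter CpG class. With the 5'-most TSS alone, high-CpG and low-CpG genes differed by 67.8 points.

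X-linked genes were marked less often than autosomal genes. TSS peaks lay at 329 of 948 X-linked genes (34.7%) and at 10704 of 20807 autosomal genes (51.4%), a difference of -16.7 percentage points (two-sided Fisher's exact p = 3.54e-24). The share was the lowest of any chromosome but Y, the next being 39.1% on chromosome 14. High-CpG promoters made up 23.8% of the X-linked and 45.7% of the autosomal genes, and within them the difference was -7.88 points (exact p = 0.00546). On chromosome Y 4 of 183 genes were marked, Kdm5d, Eif2s3y, Uty and Ddx3y, which were named after their values were seen. Of the Y promoters, 96.2% hold 50% or more repeated words and 88.5% are low-CpG.

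A further deposited list gave peaks on the earlier mm9 genome, whose coordinates were not set against mm10. It held 12654 peaks with a median width of 1935 bp that covered 27.1 Mb. Chromosome 11 carried 1070 of them and chromosome Y 8.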

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

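All tests in this part were chosen after the result was seen. Peaks on contigs lie outside the comparisons and were counted: peaks on unplaced or unlocalized contigs numbered 8 in the replicated list, 8 in the pooled list, 9 in replicate 1 and 7 in replicate 2, and were listed here because each count is above the 3 that a count of 0 allows. Nothing predicts that these contigs lack peaks, and the pooled and replicated lists draw on the reads of the replicates, so the counts say only that peaks were called there. In the replicated list they lay on 4 contigs with 2 peaks each.

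The replicate 1 list was 1.25 times as long as the replicate 2 list. After merging across 1000 bp the ratio of domains was 1.02, with 2.00 peaks per domain in replicate 1 and 1.64 in replicate 2, so more peaks per marked region may account for most of the difference. Domains numbered 25839 in replicate 1 and 25321 in replicate 2, so the net gain of separate regions in replicate 1 was small. Domains seen in 1 list alone numbered 4433 and 3666, 767 more in replicate 1. Domains are merged peaks and cannot be set directly against the difference of 10280 peaks, so some gain of separate sites is not excluded. Of the replicate 1 peaks without a replicate 2 peak, 54.9% lay within 1000 bp of one, and the rest lay farther away. The highest of 100 random placements gave 3.96%. Unshared peaks numbered 11637 in replicate 1 and 6660 in replicate 2. Merging cannot tell split peaks from extra peaks beside shared sites, so both remain open, as does the cause, since depth and background were not given, and no biological explanation was tested.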

How the results depend on the processing

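Of 412 recalculations of 51 results, 351 left a test on the same side of its threshold, a value without a test within its error or a number of lists within 1.5 times, 16 ended a call, 19 gained one, 26 moved a value without a test, and 0 reversed. The cause of the changes was not tested unless stated. The differences by CpG class, X linkage, shared peaks, peak width and summit position kept their direction and call in every alternative run, as did the TSS calls of the erythroid factor, haem and erythroid membrane lists. The X difference ranged from -17.9 to -7.88 points. Merged peaks, repeated words and nearest-TSS assignment were chosen after the data were seen. The unknown depth limits every absence of a peak.

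Overlap of replicate 1 peaks by replicate 2 was 71.1% with 50% of the query peak, 52.5% with 50% of both peaks, 89.1% with −log10 q of at least 5, 87.5% with equal numbers of the strongest peaks and 82.8% with merged peaks. Overlap of replicate 2 peaks was 74.6%, 65.5%, 77.7% and 85.5% with 50% of the query, 50% of both, equal numbers and merged peaks. The Jaccard index was 0.733 with the stricter q and 0.718 with equal numbers. With the stricter q, 99.6% of pooled peaks were in the replicated list.

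The share of peaks at a protein-coding TSS was 46.2% with a 500 bp window, 55.9% with 2500 bp, 41.5% with the 5'-most TSS, 58.9% with the stricter q, 46.2% in the pooled list, and 43.3 to 43.7% with either replicate left out. The share of genes with a TSS peak was 49.6%, 51.9%, 46.9% and 49.5% under the first 4 of these, and 50.4 to 50.9% with either replicate left out.

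Between 17 and 19 of the 23 lists passed the threshold in the alternatives with Fisher's exact test, against 18, and 12 did against lists matched on CpG class. There the list minus matched lists was -0.48 points for myeloid, -8.36 for lymphoid, -18.4 for endothelial, -18.4 for liver, -20.0 for muscle and 10.03 for histone genes, without a call. Myeloid markers (35.3%) and endothelial markers (28.6%) lost their call with a 2500 bp window. Myeloid markers also lost it with peaks given to the nearest TSS (23.5%), and endothelial markers with the stricter q (21.4%) and without replicate 2 (21.4 to 28.6% with either replicate left out). Histone genes lost it among promoters with under 10% repeated words (80.0%), where the 4 globin genes left, all embryonic or fetal, gained one (0%). Friend erythroleukaemia genes gained a call with 500 bp, the 5'-most TSS, the stricter q and nearest-TSS assignment (87.5% each), with 2500 bp (100%) and without replicate 2 (87.5 to 100% with either left out).

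The number of lists past the threshold for wide domains was 4 with the widest 10% and 4 with the stricter q, against 2. The erythroid factor list kept its call in all 7 alternatives, at 50 to 83.3%. Erythroid membrane genes lost theirs with no gap merged (15.8%), gaps of up to 3000 bp (10.5%), the widest 10% (26.3%) and without replicate 2 (20.0 to 25% with either left out). Calls were gained by Friend genes with the widest 10% (57.1%), the stricter q (42.9%) and either replicate left out (37.5 to 57.1%), by stem and progenitor genes with no gap (66.7%), by housekeeping genes without replicate 2 (4.17 to 20.8% with either left out), by the H3K4 machinery with the widest 10% (37.5%) and the stricter q (25%), by ribosomal protein genes with no gap (14.5%), 3000 bp (14.5%) and the widest 10% (23.7%), and by histone genes with 3000 bp (35.7%), which joins clustered genes by construction. Lists with under 5 marked genes in an alternative gave no value there. The wide-domain test was not rerun with the 5'-most TSS alone, with nearest-TSS assignment or against lists matched on promoter CpG class. Each gene was given the widest domain at any of its TSSs, so genes with more TSSs had more chances of a wide one.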

Other observations

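The gene families, gene types and single genes in this and the next paragraph, and the tests below except that of CpG content together with repeated sequence, were chosen after the data were seen. TSS peaks lay at 78 of 78 mitochondrial ribosomal protein genes and 34 of 34 aminoacyl-tRNA synthetase genes. They lay at 37 of 39 proteasome subunit genes, the exceptions being Psma8 and Psmb11, which encode subunits of the testis and the thymus. Genes of zinc finger proteins named Zfp were marked at 270 of 391 (69.1%), where lists matched on promoter CpG class averaged 56.8% (permutation p adjusted over 9 families = 2.2e-05, from the smallest p that the draws can give). None of 53 keratin genes, 35 Tas2r taste receptor genes or 64 defensin genes was marked in the replicated list, though 1 defensin gene was in replicate 2, nor were more than 1 of 327 vomeronasal receptor genes (Vmn1r4) and 3 of 48 genes of cytochrome P450 family 2 (Cyp2u1, Cyp2g1 and Cyp2d22). All 9 families stayed past the threshold against CpG-matched lists (permutation adjusted p of 0.011 or less). The matching did not include repeated words. Over all low-CpG promoters, 2.67% of those with 50% or more repeated words were marked, against 20.4% with under 10%. Whether this bears on the unmarked families was not tested.

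Outside protein-coding genes, 11.7% of 5854 lincRNA genes and 24.2% of 2959 antisense genes had a TSS peak. Among those farther than 5000 bp from any protein-coding TSS the shares were 7.34% of 5134 and 6.29% of 1336, with 7.77 and 7.87% for lincRNA genes in the replicate lists. Processed pseudogenes were marked at 1.19% of 8908 such loci. Mir144 and Mir451a, microRNA genes of the red cell lineage, had a TSS peak in all 3 lists examined, as did Malat1, Neat1 and Kcnq1ot1. Bloodlinc, a lincRNA gene of the red cell lineage, had none in any of the 3, nor had H19, Tsix or Xist, the RNA that silences the inactive X chromosome.

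X-linked genes were marked less often than autosomal genes, and neither promoter measure alone accounted for all of it. They numbered 85.1% of the count matched on CpG class (329 against 386, permutation p = 2e-05), and among promoters with under 10% repeated words the shares were 46.2% and 56.8%, a difference of -10.6 points (Fisher's exact p = 1.9e-07). Matching on CpG class and repeated words together left 92.3% of the matched count (329 against 357, permutation p = 0.018). The deficit was not uniform: with under 10% repeated words the X-linked and autosomal shares were 72.1% and 80.1% for high-CpG, 17.4% and 20.5% for low-CpG, but 56.4% and 55.3% for intermediate promoters, without a test by class. Both measures may contribute, since the difference shrank with each, and copy number and X-linked gene families remain open, as no biological explanation was tested.

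Of 10 globin genes 7 lacked a TSS peak. Reads shared between near-identical copies are argued against for the embryonic or fetal genes Hbb-bh1, Hbb-bh2, Hbb-y and Hba-x, since 0% of the words of their promoters occurred elsewhere. For Hbb-bs, Hba-a2 and Hbq1a, with at least 20.8% repeated words each, loss of shared reads cannot be told apart from a lack of the mark, since the handling of reads with several positions is not given. The bar, under 10% repeated words, and the grouping of the genes were set after the shares were seen. A variant of the line's own strain against the reference at the beta-globin cluster is also open and was not tested, and no biological explanation was tested, because the design has no second condition.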
